A study of Mus musculus with 4 samples.

How the data were processed

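RNA of 4 mouse Hoxb8 cell samples was profiled with a 3′ tag protocol (QuantSeq), in which priming at the poly(A) tail gives reads near the 3′ end of each transcript, so that counts need no correction for transcript length. Of the 4 libraries, 2 came from cells with an empty vector (EV) and 2 from cells expressing DNMT3A R882H, per the labels. The table holds raw counts that the authors deposited, with 1 column per library and 1 line per Ensembl gene. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.0.4, featureCounts from Subread 2.0.0, edgeR 3.34.0, limma 3.48.3 and the mm10 build were used, and their roles and settings are not given there. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

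The table has 52636 gene lines, of which 52403 were matched to a symbol through GENCODE M21 and the reference name tables. The 233 without a symbol held 0.0997% of all counts and stayed in the analysis under their Ensembl IDs. Positions are 1-based and come from GENCODE M21, which uses the same assembly as mm10; 52489 IDs have one. In the counts, 22 protocadherin gamma genes, which share their 3′ exons, had totals between 1387 and 1410 over the 4 libraries, so reads in shared exons were counted for every gene that overlaps them. Genes whose exons overlap those of another gene with at least 10 counts, on either strand, were therefore treated as uncertain: 3501 of the 11444 tested genes and 1285 of the 4435 called ones. Whether reads of paralogs and processed pseudogenes, as of ribosomal protein, histocompatibility and globin genes, were separated was not tested.

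Total counts were 5470330 and 5605092 in the EV libraries and 5921985 and 5847609 in the R882H libraries. A count of 0 allows up to 3 counts, which is 0.507 to 0.548 CPM. Intervals on counts are exact 95% intervals and cover counting error only. Libraries of a group were compared before averaging. Their log2 CPM correlated across genes with Pearson r = 0.986 in EV and 0.988 in R882H, against 0.900 to 0.908 between groups. The chi-square per degree of freedom of the counts within a group was 6.91 for EV and 4.61 for R882H, so neither pair was 1 library deposited a second time.

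Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, glmQLFit with robust estimation and glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A gene is said to have risen, fallen or been called only past that threshold. CPM values use the TMM-scaled library sizes and are means ± SD. Log2 fold changes are R882H over EV. Their standard error was computed as the absolute log2 fold change over the square root of the F statistic. Where a group held few counts and the fold is large, this value can fall below counting error and overstates the precision. The common biological coefficient of variation was 0.0957. Where a group held no counts of a gene, a lower bound of the fold was taken against 3 counts over the group. Where it held 1 to 3, the ratio of normalised counts is given with its interval, since the fitted fold then depends on the prior count.

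There were 34 gene lists, fixed before the data were examined, and the 30 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 30. Camera with an estimated correlation and fry, which asks whether a list differs from no change instead of from the other genes, were run beside it. Each list's members were also counted with p-values adjusted over the list alone. The genes named in the text were set by a rule written before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 10 CPM, both R882H libraries on one side of both EV libraries and an established symbol. It also took Dnmt3a, Dnmt1, Dnmt3b, Hoxb8 and all heme biosynthesis genes. From each list past the set test or with at least 3 called members it took up to 4 members with the smallest p and up to 2 that moved the other way, and from lists of other cell types and of RNA quality the 3 with the most counts. Sex-linked genes, members named to complete a count of 5 or fewer, and gene families by shared symbol were chosen after their values were seen; the gene-level alternatives were run for the completing and family members too, outside the count of 184 named genes. Some genes that meet the rule are not reported here.

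Counts were simulated for the same 11444 genes and library sizes, with 50 genes changed at each of 4 fold sizes. The edgeR test recovered 34% of genes changed 1.5-fold, 70% at 2-fold, 96% at 4-fold and 98% at 8-fold. Of 157 calls, 8 were false. Far more genes were called in the data (4435), so these recovery rates need not carry over. In the simulated set test, genes were drawn independently of each other. Camera with the preset correlation called the planted list (adjusted p = 1.86e-14), whereas camera with an estimated correlation missed it (adjusted p = 0.39). Fry called it (adjusted p = 0.0462) with 1 unchanged list. The simulation cannot show how the preset does for lists whose genes vary together. Alternatives were DESeq2 size factors within edgeR, library size alone, no low-count filter, at least 10 counts in every library of a group, the replicate number as a block, robust=FALSE, leaving out each library in turn, a minimum fold of 1.2 with glmTreat, a threshold of 0.01, limma-voom, DESeq2 1.42.0, fry, an estimated correlation and a prior count of 0.5. Leaving out genes with overlapping exons was added after the data were seen.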

Results

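Gene expression was measured in mouse Hoxb8 cells, a cell line named for the homeobox gene Hoxb8; lines immortalised with this gene are widely used as models of myeloid progenitors. The 2 groups were cells with an empty vector (EV, n = 2 libraries) and cells expressing DNMT3A R882H (R882H, n = 2), a recurrent substitution of the de novo DNA methyltransferase DNMT3A in acute myeloid leukaemia. Each library held between 5470330 and 5921985 counts. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples. All CPM values below are means ± SD with n = 2 per group, and log2 fold changes (R882H over EV) carry a standard error from the edgeR fit over the same 4 libraries.

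The comparison asked which transcripts differ between cells with the DNMT3A variant and cells with the vector alone, in a series about heme biosynthesis and copper-dependent death of leukaemia cells. The R882H cells gained Mpo, the myeloperoxidase of neutrophil granules (gene ENSMUSG00000009350, mm10 chromosome 11, 87793581 to 87804413), from 32.7 ± 3.19 CPM in EV to 1242 ± 40.5 CPM in R882H, a log2 fold change of 5.25 ± 0.17 (edgeR adjusted p = 2.45e-23). They lost Cited1, a transcriptional co-regulator (ENSMUSG00000051159, chromosome X, 102247381 to 102252181), which had 1744 ± 19.9 CPM in EV and 2.71 ± 1.60 CPM in R882H (log2 fold change −9.30 ± 0.24, edgeR adjusted p = 1.12e-25). The chemokine Pf4 had 939 ± 134 CPM in EV and 12.8 ± 3.20 CPM in R882H (log2 fold change −6.19 ± 0.19), and the surface glycoprotein Thy1 had 659.9 ± 62.9 CPM in EV and 9.64 ± 2.46 CPM in R882H (log2 fold change −6.09 ± 0.19). Satb1, a chromatin organiser of lymphoid cells, rose from 3.25 ± 0.851 CPM in EV to 180.1 ± 16.1 CPM in R882H (log2 fold change 5.79 ± 0.20), and the surrogate light chain gene Vpreb3 rose with a log2 fold change of 5.78 ± 0.22.

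Several of the largest rises started from almost no EV transcript. Whether these rises share a source with the Y-linked transcripts of the same R882H libraries, described below, was not tested. The basophil protease gene Prss34 (chromosome 17, 25298394 to 25300165) had counts of 1, 0, 241 and 211 in EV replicates 1 and 2 and R882H replicates 1 and 2, a ratio of 431, 95% interval 76.9 to 17041. Arap2 had a ratio of 309, 95% interval 85.2 to 2558, Tfec of 254, 95% interval 45.3 to 10082, Scin of 168, 95% interval 46.2 to 1394 and Tdrkh of 85.4, 95% interval 28.9 to 417. Log2 fold changes were 6.98 ± 0.28 for Pi15 and 6.55 ± 0.30 for Cd24a, a surface glycoprotein gene. Among the largest falls, Mtus2 and Fstl1 had no counts in R882H and were at least 105-fold and 94.8-fold lower, and Add2, an adducin of the membrane skeleton, had a ratio of EV over R882H of 843, 95% interval 151 to 33341. Log2 fold changes were −8.57 ± 0.25 for Serpinb12, −7.66 ± 0.24 for the glypican gene Gpc3, −6.58 ± 0.37 for the granule protein gene Lcn2 and −6.55 ± 0.32 for the BMP receptor gene Bmpr1a. They were −6.45 ± 0.30 for Sim2 and −6.24 ± 0.37 for the VEGF receptor gene Flt1, which had 6 and 0 counts in R882H, so that without R882H replicate 1 its fold has only a lower bound. The exons of Pi15, Tdrkh and Add2 overlap those of Gm28154, Oaz3 and Gm44089, and their reads cannot be told apart. Intervals on ratios and floors cover counting error only. The standard errors above are too small where a group held few counts. Examples are Serpinb12 (5 and 2 in R882H), Lcn2 (3 and 1 in R882H) and Pi15 (4 and 3 in EV).

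Of 11444 genes tested, 2213 were higher and 2222 lower in R882H (38.8%, edgeR quasi-likelihood test). Of these, 895 rose and 721 fell by at least 2-fold, 200 and 122 by at least 8-fold, and 2819 differed by less than 2-fold. DESeq2 called fewer genes, 1297 higher and 1412 lower, and without R882H replicate 1 edgeR called 1508 higher and 1446 lower.

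**Figure D1:**
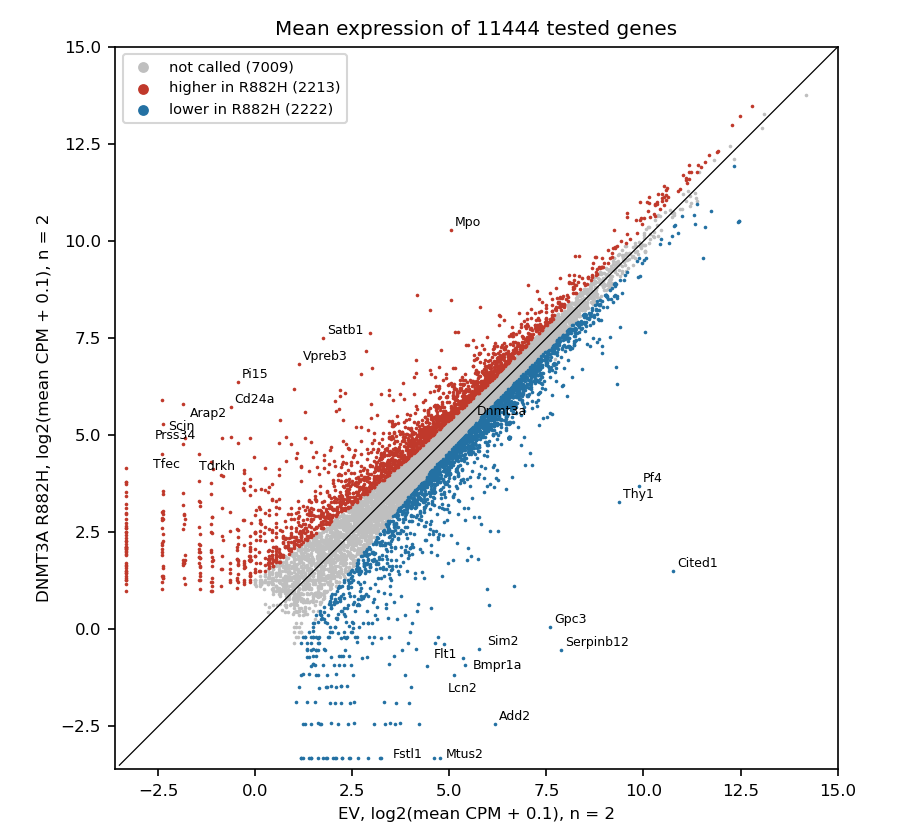
Mean expression of the 11444 tested genes in EV (horizontal axis) and DNMT3A R882H (vertical axis), as log2 of the mean CPM plus 0.1, with n = 2 libraries per group and 1 point per gene. Red points (2213) were higher and blue points (2222) lower in R882H by edgeR, grey points were not called, and the line marks equal expression; Mpo lies far above it and Cited1 far below.

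The 3 DNA methyltransferase genes themselves were not called. The endogenous and any vector-borne Dnmt3a could not be separated: counts of Dnmt3a (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443) were 264, 270, 254 and 239, or 48.0 ± 0.535 CPM in EV and 42.2 ± 0.386 CPM in R882H (log2 fold change −0.19 ± 0.15, edgeR adjusted p = 0.334). Tags at the 3′ end of the gene need not cover a transgene, so this value does not check the group labels. The maintenance methyltransferase Dnmt1 had 252 ± 49.8 CPM in EV and 247 ± 8.11 CPM in R882H and the de novo enzyme Dnmt3b 20.7 ± 3.38 CPM in EV and 18.1 ± 3.40 CPM in R882H (log2 fold changes −0.03 ± 0.14 and −0.20 ± 0.19, edgeR adjusted p = 0.891 and 0.446). The sign for Dnmt1 turned without EV replicate 2 (0.18) and without R882H replicate 2 (0.02). Dnmt3b had −0.36 without EV replicate 1 and −0.02 without EV replicate 2. It had −0.001 without R882H replicate 1 and −0.38 without R882H replicate 2. Of the DNA methylation list's 14 tested members, 1 rose, 2 fell and 11 did not pass the test, with the same counts when adjusted over the list alone. The methyl-CpG binding genes Zbtb38 (−0.76 ± 0.15) fell and Mbd1 (0.50 ± 0.14) rose, and the dioxygenase gene Tet3 (−0.71 ± 0.21) fell, on the log2 scale. The call ended for Mbd1 without R882H replicate 1 (0.106) and in DESeq2 (0.0552) and for Tet3 without EV replicate 2 (0.0503), without R882H replicate 2 (0.129) and in DESeq2 (0.106), where brackets give the adjusted p by edgeR, here and below, or by the tool named. The list did not pass the set test (camera adjusted p = 0.687). Of 16 germline genes that DNA methylation silences in somatic cells, Sycp3 alone had enough counts to be tested. It was not called with all 4 libraries (0.59 ± 0.35). Its log2 fold change depended on the EV library, with 1.17 without EV replicate 1 and 0.17 without EV replicate 2. The exons of Sycp3 overlap Chpt1. Of 5 tested imprinted genes, 2 rose, the Notch ligand homologue Dlk1 (3.56 ± 0.22) and the antisense RNA Kcnq1ot1 (0.67 ± 0.14), also when adjusted over the list alone (list camera adjusted p = 0.596).

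In heme biosynthesis, 3 enzymes fell and none rose. Counts of called members, here and in the lists below, stand beside 38.8% called among all tested genes. Alad, which makes porphobilinogen (ENSMUSG00000028393, chromosome 4, 62509169 to 62519918), had 24.1 ± 3.42 CPM in EV and 9.06 ± 1.39 CPM in R882H (log2 fold change −1.41 ± 0.21, edgeR adjusted p = 1.69e-06). Urod (chromosome 4, 116989965 to 116994413), which decarboxylates uroporphyrinogen, had 58.5 ± 2.62 CPM in EV and 33.9 ± 7.93 CPM in R882H (−0.79 ± 0.16, adjusted p = 0.000141). Ppox, the mitochondrial protoporphyrinogen oxidase, had 32.6 ± 7.51 CPM in EV and 22.3 ± 0.214 CPM in R882H (−0.55 ± 0.18, adjusted p = 0.0133). The first enzyme, Alas1, had 56.2 ± 10.2 CPM in EV and 51.9 ± 0.0637 CPM in R882H (−0.11 ± 0.15, adjusted p = 0.566), and Uros (−0.13 ± 0.30), Cpox (−0.20 ± 0.16) and the ferrochelatase gene Fech (−0.16 ± 0.20) were not called either. Signs turned for Alas1 (0.08) and Fech (0.02) without EV replicate 2, and for Uros without EV replicate 1 (0.06) and R882H replicate 2 (0.06). Alas2, the erythroid form, had 1 count in all 4 libraries and was not tested. The same 3 of 8 tested members fell when adjusted over the list alone, the median log2 fold change was −0.18, and the list did not pass the set test (camera adjusted p = 0.183). The Ppox call ended without EV replicate 2 (0.249, log2 fold change −0.30), without R882H replicate 1 (0.0765), without R882H replicate 2 (0.0806) and in DESeq2 (0.123), and its exons overlap B4galt3.

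Genes of heme transport and turnover fell more often than they rose. Of the list's 17 tested members, 1 rose, 6 fell and 10 did not pass the test, also when adjusted over the list alone. The heme oxygenase gene Hmox1 had 6.10 ± 1.11 CPM in EV and 0.765 ± 0.338 CPM in R882H (log2 fold change −2.95 ± 0.48, edgeR adjusted p = 7.16e-06), and the mitochondrial transporter Abcb10 had 67.2 ± 5.12 CPM in EV and 35.7 ± 3.76 CPM in R882H (−0.91 ± 0.15). The transporter genes Slc46a1 (−3.02 ± 0.62) and Slc48a1 (−0.67 ± 0.14) fell, and the mitochondrial iron importer Slc25a37 rose (0.39 ± 0.13). Slc46a1 lost its call without EV replicate 1 (0.0553), Slc48a1 without R882H replicate 1 (0.0536) and Slc25a37 without EV replicate 1 (0.0951), without R882H replicate 1 (0.0633), without R882H replicate 2 (0.164) and in DESeq2 (0.0825). The list did not pass the set test (camera adjusted p = 0.228). In iron handling, 2 of 19 tested members fell, the ferritin light chain gene Ftl1 (467 ± 34.6 CPM in EV and 179 ± 3.64 CPM in R882H, −1.39 ± 0.13) and the iron regulator Hfe (−1.51 ± 0.26). The reductase gene Steap3 (1.09 ± 0.17) and the iron-sulphur co-chaperone gene Hscb (1.11 ± 0.18) rose, with the same counts when adjusted over the list alone (list camera adjusted p = 0.687). The Steap3 call ended without EV replicate 1 (0.0753) and without EV replicate 2 (0.0651). The exons of Abcb10, Slc48a1 and Ftl1 overlap Gm45890, Hdac7 and Gm22133.

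Copper-binding metallothioneins fell. Mt2 (chromosome 8, 94172664 to 94173568) had 1043 ± 167 CPM in EV and 202 ± 0.179 CPM in R882H (log2 fold change −2.37 ± 0.15, edgeR adjusted p = 3.71e-15) and Mt1 had 1705 ± 226 CPM in EV and 1112 ± 27.8 CPM in R882H (−0.62 ± 0.15, adjusted p = 0.000907). The copper exporter Atp7a (−1.45 ± 0.47) and the chaperone Atox1 (−0.40 ± 0.13) also fell, so that 4 of 14 tested copper transport genes fell and none rose, with the same counts when adjusted over the list alone. Atp7a lost its call without EV replicate 2 (0.146), without R882H replicate 2 (0.216) and in DESeq2 (0.178), and Atox1 without R882H replicate 1 (0.155), without R882H replicate 2 (0.135) and in DESeq2 (0.0525). The list missed the threshold (camera adjusted p = 0.0865) and passed it without EV replicate 2 (adjusted p = 0.0352). Fry, which tests a list against no change instead of against the other genes, gave adjusted p = 0.0258 here. Mt2 shares exon positions with the antisense gene Gm45774, which had 2814, 4360, 469 and 460 counts. Of 15 genes of protein lipoylation and cuproptosis, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.945). The ferredoxin gene Fdx1 rose from 10.1 ± 1.89 CPM in EV to 17.4 ± 2.32 CPM in R882H (0.78 ± 0.22), and Cdkn2a, a cell cycle inhibitor on this list, had counts of 0, 2, 69 and 64, a ratio of 63.3, 95% interval 17.2 to 528. The pyruvate dehydrogenase subunit gene Dlat (−0.50 ± 0.14), the glycine cleavage gene Gcsh (−0.53 ± 0.15) and the metal-responsive factor gene Mtf1 (−0.37 ± 0.14) fell. Fdx1 lost its call without EV replicate 1 (0.0728), without R882H replicate 1 (0.0725) and in DESeq2 (0.0984), and Dlat without R882H replicate 2 (0.115) and in DESeq2 (0.0519). Gcsh lost it without R882H replicate 2 (0.0551), and Mtf1 without EV replicate 1 (0.153), without R882H replicate 1 (0.169), without R882H replicate 2 (0.211) and in DESeq2 (0.173). Exons of Mtf1 overlap 1110065P20Rik.

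**Figure D2:**
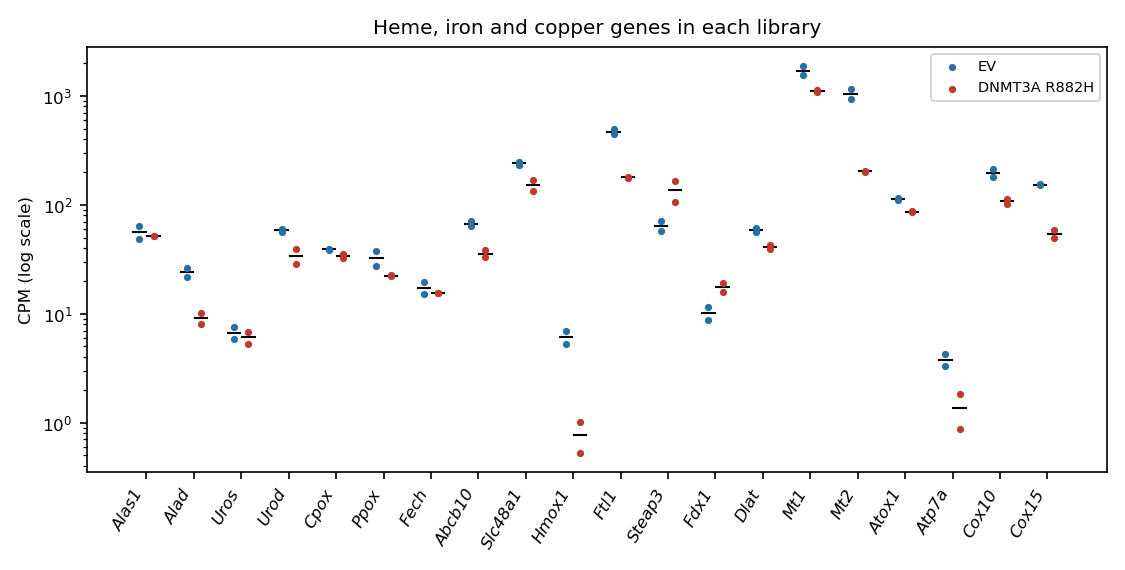
CPM (log axis) of heme, iron and copper genes in each of the 2 EV libraries (blue) and 2 R882H libraries (red), with group means as black bars. Alad, Hmox1, Ftl1 and Mt2 lie lower in both R882H libraries than in both EV libraries, whereas Alas1 and Fech overlap or nearly meet.

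Mitochondrial respiration genes moved in both directions. Both enzymes that make heme a for complex IV fell, Cox15 with 153 ± 2.73 CPM in EV and 54.0 ± 6.07 CPM in R882H (−1.51 ± 0.14, edgeR adjusted p = 4.91e-11) and Cox10 with 195 ± 22.1 CPM in EV and 108 ± 8.74 CPM in R882H (−0.86 ± 0.13, adjusted p = 4.18e-06). In the same list of 15 tested members 5 rose, also when adjusted over the list alone: Ndufa4 (128 ± 6.13 CPM in EV and 256 ± 12.1 CPM in R882H), Cox7a2l (0.76 ± 0.14), Cox4i1 (0.46 ± 0.15), Cox6c (0.58 ± 0.15) and Cox7b (0.40 ± 0.16) (list camera adjusted p = 0.945). Cox4i1 lost its call without EV replicate 2 (0.171, log2 fold change 0.22) and without R882H replicate 2 (0.124), with a log2 fold change of 0.73 without EV replicate 1, and Cox6c without R882H replicate 2 (0.0547). Cox7b lost it with DESeq2 size factors in edgeR (0.0565), with at least 10 counts in every library of a group (0.0505), with robust=FALSE (0.0573), without EV replicate 2 (0.616, log2 fold change 0.09), without R882H replicate 1 (0.155), without R882H replicate 2 (0.0972), without genes whose exons overlap another gene (0.0625) and in DESeq2 (0.136), with a log2 fold change of 0.78 without EV replicate 1. The exons of Cox15 overlap Cutc and Entpd7, and those of Cox10 overlap 9630013K17Rik. Of 30 genes of complexes I, II, III and V, 4 rose (2 when adjusted over the list alone) and 5 fell (also 5; camera adjusted p = 0.687). The complex III genes Cyc1 (−0.95 ± 0.13) and Uqcrc1 (−0.89 ± 0.14) fell, as did Atp5d (−0.58 ± 0.14), Uqcrq (−0.40 ± 0.13) and Ndufa9 (−0.37 ± 0.14), and Sdhb (0.50 ± 0.13), Atp5o (0.43 ± 0.14), Ndufa1 (0.36 ± 0.14) and Ndufb3 (0.36 ± 0.14) rose. Sdhb lost its call without R882H replicate 2 (0.0621), Atp5d without R882H replicate 1 (0.153) and Ndufa1 without EV replicate 2 (0.369, log2 fold change 0.16), without R882H replicate 1 (0.0802), without R882H replicate 2 (0.249) and in DESeq2 (0.150), with a log2 fold change of 0.59 without EV replicate 1. Atp5o lost it without EV replicate 2 (0.0530), without R882H replicate 1 (0.0670) and without R882H replicate 2 (0.153), and Uqcrq without EV replicate 1 (0.0846), without R882H replicate 1 (0.221) and without R882H replicate 2 (0.111). Ndufa9 lost it without EV replicate 2 (0.0613), without R882H replicate 1 (0.0706), without R882H replicate 2 (0.352) and in DESeq2 (0.143). Ndufb3 lost it with DESeq2 size factors in edgeR (0.0541), with at least 10 counts in every library of a group (0.0502), with robust=FALSE (0.0538), without EV replicate 2 (0.346, log2 fold change 0.16), without R882H replicate 1 (0.0910), without R882H replicate 2 (0.329), without genes whose exons overlap another gene (0.0530) and in DESeq2 (0.101), with a log2 fold change of 0.57 without EV replicate 1. In the tricarboxylic acid cycle, 5 of 11 genes fell, including Ogdh (−0.73 ± 0.13) and Mdh2 (−0.77 ± 0.15), with Cs (−0.53 ± 0.13) and Idh3a (−0.39 ± 0.13). Suclg2 (0.66 ± 0.13) and Fh1 (0.33 ± 0.13) rose, with the same counts when adjusted over the list alone. This list's median (0.05) and mean (−0.13) differ in sign, and camera's direction was downward (adjusted p = 0.687). Cs lost its call without R882H replicate 2 (0.0528). Fh1 lost it with library size only (0.0527), without a low-count filter (0.0508), with the replicate block (0.0512), without EV replicate 1 (0.0657), without EV replicate 2 (0.0545), without R882H replicate 1 (0.0943), without R882H replicate 2 (0.354) and in DESeq2 (0.105). Idh3a lost its call without EV replicate 1 (0.0734), without R882H replicate 1 (0.306), without R882H replicate 2 (0.0685) and in DESeq2 (0.0653). Exons of Atp5d, Cox4i1, Cox6c and Ndufa9 overlap Cbarp, Emc8, Vps13b and 1700018A23Rik.

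Genes of the amino acid response driven by ATF4 fell more often than they rose. Of the ATF4 list's 20 tested members, 2 rose, 14 fell and 4 did not pass the test, with the same counts when adjusted over the list alone. The transcription factor gene Atf5 had 75.4 ± 9.92 CPM in EV and 17.0 ± 0.818 CPM in R882H (log2 fold change −2.15 ± 0.16, edgeR adjusted p = 5.39e-13) and the amino acid transporter gene Slc7a5 had 166 ± 39.4 CPM in EV and 73.8 ± 3.11 CPM in R882H (−1.17 ± 0.15). The biosynthetic genes Psat1 (−0.88 ± 0.13) and Aldh18a1 (−1.04 ± 0.17) fell, whereas Cebpg (0.60 ± 0.14) and Ddit4 (0.57 ± 0.15) rose, and Atf4 itself was not called (−0.13 ± 0.14; 0.04 without EV replicate 1). The median log2 fold change was −0.74 (camera adjusted p = 0.000510). The call was lost, with adjusted p = 0.697 with an estimated correlation. The exons of Atf5 overlap Il4i1 and Nup62. Those of Cebpg overlap Gm44836.

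The other metabolic lists did not pass camera with all 4 libraries and the low-count filter. Of 13 tested NRF2 targets, 7 fell (9 when adjusted over the list alone), among them the antioxidant genes Srxn1 (−1.48 ± 0.18), Gsr (−1.02 ± 0.14) and G6pdx (−0.77 ± 0.14). The quinone reductase gene Nqo1 rose (2.78 ± 0.53). The list's camera adjusted p was 0.0676, with 0.0395 without EV replicate 1 and 0.00853 without a low-count filter. Of 20 cholesterol synthesis genes, 6 fell and none rose, also when adjusted over the list alone, among them Mvd (48.0 ± 2.44 CPM in EV and 29.8 ± 0.284 CPM in R882H, −0.69 ± 0.16), the sterol regulator gene Srebf2 (−0.63 ± 0.15) and Fdps (−0.50 ± 0.13), with camera adjusted p = 0.141 (fry adjusted p = 0.0322). Srebf2 lost its call without EV replicate 2 (0.0519, log2 fold change −0.35), and Fdps without R882H replicate 1 (0.0524) and without R882H replicate 2 (0.0750). Of 21 genes of glycolysis and the hypoxia response, 7 rose and 8 fell, also when adjusted over the list alone. The hypoxia-induced genes Ankrd37 (2.72 ± 0.30) and Bnip3 (25.2 ± 0.337 CPM in EV and 50.3 ± 13.3 CPM in R882H) and the phosphofructokinase gene Pfkl (0.77 ± 0.13) rose and the hexokinase gene Hk2 (−1.26 ± 0.14) fell. That list's median (−0.08) and mean (0.07) differ in sign, with camera downward (adjusted p = 0.935). Of 18 genes of Myc activity and ribosome biogenesis, 7 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.127, fry adjusted p = 0.0322). The nucleolar genes Bop1 (−0.92 ± 0.15) and Rrp9 (−0.79 ± 0.17) fell, and Myc itself rose (0.58 ± 0.15), a call that ended without EV replicate 1 (0.0562, log2 fold change 0.34) and without R882H replicate 1 (0.0569). Exons of Fdps, Ankrd37, Bnip3, G6pdx, Bop1 and Rrp9 overlap Gm43738, Ufsp2, Gm45507, Ikbkg, Mroh1 and Parp3.

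Regulators of stem and progenitor cells changed in both directions. Of the list's 16 tested members, 7 rose, 5 fell and 4 did not pass the test, with the same counts when adjusted over the list alone (camera adjusted p = 0.870). The receptor gene Kit rose from 26.5 ± 8.70 CPM in EV to 77.6 ± 13.4 CPM in R882H (1.55 ± 0.17), and Mycn had no counts in EV and 39 and 26 in R882H, at least 20.6-fold higher. Pbx3, a Hox cofactor, had 123 ± 12.3 CPM in EV and 18.8 ± 3.42 CPM in R882H (−2.71 ± 0.16), and Gata2 (−0.86 ± 0.17) and Bcat1 (−0.88 ± 0.17) fell. Hoxb8 counts at chromosome 11, 96281905 to 96285315 were 25, 44, 15 and 4 (−1.92 ± 0.45, edgeR adjusted p = 0.000824), a call that ended without EV replicate 2 (0.0652), with a log2 fold change of −3.09 without R882H replicate 1; whether these tags cover the construct behind the line's name is not known.

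Neutrophil granule genes did not move as 1 group. Of 12 primary granule and promyelocyte genes, 4 rose and 4 fell, also when adjusted over the list alone. Mpo, the cytotoxic granule gene Nkg7 (2.72 ± 0.25) and Plac8 (608 ± 59.0 CPM in EV and 1250.4 ± 18.5 CPM in R882H, 1.04 ± 0.14) rose with Ctsg (0.61 ± 0.14), whereas Gstm1 (−2.03 ± 0.15) and the transcription factor genes Gfi1 (−0.96 ± 0.14) and Cebpa (−0.74 ± 0.14) fell with Ms4a3 (−0.49 ± 0.16). The elastase gene Elane (0.54 ± 0.31) and the proteinase gene Prtn3 (−0.04 ± 0.13) were not called. With 1 library left out, the Elane value lay between 0.29 (without EV replicate 2) and 0.82 (without EV replicate 1). The list's median was −0.08 and its mean 0.47, with camera in the upward direction (adjusted p = 0.870; fry adjusted p = 0.0258). Of 8 tested secondary granule and late neutrophil genes, 2 rose, Fcnb (1.52 ± 0.26) and Mmp8 (0.40 ± 0.13), and 2 fell, Lcn2 (−6.58 ± 0.37) and Anxa1 (−0.85 ± 0.13), also when adjusted over the list alone. The median was 0.14, the mean −0.64 and the camera direction downward (adjusted p = 0.935), and the Mmp8 call ended without R882H replicate 1 (0.0594) and without R882H replicate 2 (0.188). Of 11 tested monocyte and macrophage markers, 6 rose (7 when adjusted over the list alone) and 3 fell (camera adjusted p = 0.104). The list passed without a low-count filter (camera adjusted p = 0.00683) and without genes with overlapping exons (camera adjusted p = 0.0448), and fry gave adjusted p = 0.0322 against no change. The transcription factor gene Irf8 had 14.0 ± 1.52 CPM in EV and 81.1 ± 2.22 CPM in R882H (2.54 ± 0.16), and F13a1 (2.51 ± 0.14), the protease gene Ctss (4.24 ± 0.31) and the chemokine receptor gene Ccr2 (1.19 ± 0.14) rose. The surface marker genes Cd14 (−2.94 ± 0.43), Adgre1 (−1.89 ± 0.27) and Ms4a6c (−0.94 ± 0.17) fell. Ms4a3 lost its call without EV replicate 1 (0.302, log2 fold change −0.21), without R882H replicate 1 (0.181) and in DESeq2 (0.0968). Exons of Gfi1, Prtn3 and Ms4a6c overlap A430072P03Rik, Plppr3 and BE692007.

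Early lymphoid genes rose in R882H. The lymphoid list had 16 members, and those with too few counts were not tested. A member without EV counts, such as Pax5, passed the low-count filter only through its R882H counts and could only come out higher. All 9 tested members were higher, also when adjusted over the list alone, with a median log2 fold change of 1.63 (camera adjusted p = 1.11e-05). That call was lost, with adjusted p = 0.697 with an estimated correlation. The surrogate light chain genes Vpreb1 (chromosome 16, 16868403 to 16870843) and Igll1 had 17.8 ± 3.91 CPM in EV and 388 ± 14.6 CPM in R882H (4.45 ± 0.17), and 325 ± 2.79 CPM in EV and 787 ± 54.5 CPM in R882H (1.28 ± 0.14). The terminal transferase gene Dntt had 79.6 ± 3.19 CPM in EV and 269 ± 14.6 CPM in R882H (1.76 ± 0.14), the B-lineage factor gene Ebf1 179.9 ± 6.26 CPM in EV and 289 ± 20.4 CPM in R882H (0.69 ± 0.13), and Pax5 counts were 0, 0, 102 and 61, at least 51.8-fold higher in R882H. Cd74, a marker of mature B cells, had 1, 1, 2 and 1 counts. The exons of Vpreb1 overlap Top3b and those of Pax5 overlap 5730488B01Rik.

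Markers of other lineages moved as well. The mast cell, basophil and eosinophil list had 14 members, and those with too few counts were not tested. Prss34, with 1 and 0 counts in EV, passed the low-count filter only through its R882H counts. Of 5 tested mast cell, basophil and eosinophil genes 4 rose (5 when adjusted over the list alone): the carboxypeptidase gene Cpa3 (22.5 ± 1.68 CPM in EV and 300.0 ± 17.3 CPM in R882H, 3.74 ± 0.15), Prss34, the protease gene Mcpt8 (20.5 ± 0.3 CPM in EV and 44.3 ± 0.411 CPM in R882H, 1.11 ± 0.17) and Hdc (0.71 ± 0.26). The list passed the set test (camera adjusted p = 0.00225) and lost the call, with adjusted p = 0.697 with an estimated correlation, and the Hdc call ended without EV replicate 2 (0.207), without R882H replicate 2 (0.355, log2 fold change 0.44) and in DESeq2 (0.226). Of 6 tested megakaryocyte and platelet genes 3 fell, Pf4, Ppbp (−5.57 ± 0.42; 5 and 0 counts in R882H, so only bounded without R882H replicate 1) and Itgb3 (−0.39 ± 0.16), and Itga2b rose (1.35 ± 0.38; 2 rose when adjusted over the list alone; list camera adjusted p = 0.687). Itgb3 lost its call without a low-count filter (0.0540), with robust=FALSE (0.0552), without EV replicate 2 (0.335, log2 fold change −0.22), without R882H replicate 1 (0.156), without R882H replicate 2 (0.233), in limma-voom (0.0569) and in DESeq2 (0.210). Itga2b lost it without R882H replicate 1 (0.0514) and in DESeq2 (0.0976). Of 4 tested genes of antigen presentation, the class II genes H2-Ab1 (−1.39 ± 0.19) and H2-Eb1 (17, 16, 0 and 1 counts, a ratio of EV over R882H of 34.6, 95% interval 5.80 to 1409) fell and H2-DMa (1.05 ± 0.16) and H2-DMb1 (1.48 ± 0.26) rose. Of 4 tested erythroid genes, the carbonic anhydrase gene Car2 fell (485 ± 0.520 CPM in EV and 139.6 ± 18.4 CPM in R882H, −1.79 ± 0.14), and Tal1 (0.04 ± 0.14; −0.09 without EV replicate 1) and Hbb-bt (−0.42 ± 0.27) were not called. Of 2 tested fibroblast and stromal genes, Thy1 and Fn1 (−2.64 ± 0.64) fell, and the Fn1 call ended without EV replicate 1 (0.0595). In these 3 lists, too small for the set test, the counts were the same when adjusted over the list alone. Exons of H2-DMa overlap Brd2.

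Y-linked transcripts were found in the R882H libraries beside these lineage changes. Counts were 0, 2, 65 and 41 for Ddx3y (chromosome Y, 1260771 to 1286629; ratio of R882H over EV 50.5, 95% interval 13.6 to 422) and 1, 0, 26 and 29 for Eif2s3y (ratio 52.4, 95% interval 9.02 to 2106). Kdm5d had 1, 2, 7 and 7 and Uty 0, 0, 12 and 10. The 4 genes together had 6 counts in EV and 197 in R882H, which is 0.0829% (exact 95% interval 0.0304 to 0.181) and 2.82% (2.44 to 3.25) of the counts of their X-linked homologues Ddx3x, Eif2s3x, Kdm5c and Kdm6a. Xist, the RNA that coats an inactive X chromosome, had 261 ± 10.2 CPM in EV and 289.7 ± 35.1 CPM in R882H (0.15 ± 0.13, edgeR adjusted p = 0.392), and its exons overlap those of Tsix.

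Innate immune genes included falls of the RNA sensor genes. Of 11 tested interferon-stimulated genes 4 fell and none rose, also when adjusted over the list alone: Ifih1 (30.5 ± 0.0666 CPM in EV and 8.48 ± 0.0760 CPM in R882H, −1.84 ± 0.20), Ddx58 (−1.28 ± 0.25), Rtp4 (−1.09 ± 0.21) and Bst2 (−0.86 ± 0.17). The list's camera adjusted p was 0.0861, 0.00737 without R882H replicate 1, 0.0234 without R882H replicate 2 and 0.00683 without a low-count filter, and fry's was 0.0304. Of 12 tested NF-kB and cytokine genes 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.945, upward, against a median of −0.06 and a mean of −0.19). The chemokine genes Ccl3 (19.7 ± 2.19 CPM in EV and 57.4 ± 8.23 CPM in R882H, 1.54 ± 0.17) and Ccl4 (3.35 ± 0.61; 5 and 0 counts in EV, so only bounded without EV replicate 1) rose with Il6 (3.21 ± 0.62) and Nfkbiz (1.24 ± 0.34). Cxcl2 had no counts in R882H and 26 and 32 in EV, at least 20.3-fold lower, and Ptgs2 (−2.22 ± 0.59) and Icam1 (−0.89 ± 0.24) fell. Ptgs2 lost its call without R882H replicate 2 (0.0917) and in DESeq2 (0.0830) and Icam1 without EV replicate 2 (0.0701) and in DESeq2 (0.0688). Nfkbiz lost it without R882H replicate 1 (0.110) and in DESeq2 (0.0907). Exons of Icam1 overlap Gm47079.

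Of 13 tested p53 targets, 7 rose and 3 fell (4 when adjusted over the list alone; camera adjusted p = 0.687). The cell cycle inhibitor gene Cdkn1a had 17.0 ± 4.63 CPM in EV and 90.0 ± 12.3 CPM in R882H (2.40 ± 0.17, edgeR adjusted p = 8.08e-14), and Ccng1 (1.45 ± 0.17) and Sesn1 (1.07 ± 0.16) rose. Gdf15 (−3.96 ± 0.35), the death receptor gene Fas (−2.60 ± 0.66) and Pmaip1 (−0.60 ± 0.17) fell, and the call ended for Fas without EV replicate 1 (0.0685), without R882H replicate 1 (0.0922) and in DESeq2 (0.0637) and for Pmaip1 without R882H replicate 2 (0.0646). Of 17 mitotic genes, Cdk1 (0.51 ± 0.14), Nusap1 (0.55 ± 0.14) and Top2a (0.36 ± 0.13) rose and Plk1 (−0.33 ± 0.13) fell. When adjusted over the list alone 2 rose and none fell (camera adjusted p = 0.870). Cdk1 lost its call without R882H replicate 2 (0.0547) and Nusap1 without R882H replicate 2 (0.0558). Top2a lost it with the replicate block (0.0528), without R882H replicate 1 (0.105) and without R882H replicate 2 (0.3). Plk1 lost it without a low-count filter (0.0636), with the replicate block (0.0521), with robust=FALSE (0.0519), without EV replicate 2 (0.151), without R882H replicate 1 (0.493, log2 fold change −0.21), without R882H replicate 2 (0.102) and in DESeq2 (0.0721). Of 17 DNA replication genes, Tk1 (0.71 ± 0.14), Mcm6 (0.47 ± 0.13) and Gins2 (0.33 ± 0.13) rose and Rrm2 (−0.62 ± 0.13) and Cdc45 (−0.39 ± 0.14) fell. When adjusted over the list alone 2 rose and 2 fell, and the median (0.09) was positive while camera's direction was downward (adjusted p = 0.945). Tk1 lost its call without R882H replicate 2 (0.0508), Mcm6 without R882H replicate 1 (0.0866) and without R882H replicate 2 (0.0502) and Cdc45 without EV replicate 1 (0.113), without R882H replicate 1 (0.169), without R882H replicate 2 (0.159) and in DESeq2 (0.148). Gins2 lost it with DESeq2 size factors in edgeR (0.0508), with library size only (0.0527), without a low-count filter (0.0543), with the replicate block (0.0516), without EV replicate 2 (0.120), without R882H replicate 1 (0.200), without R882H replicate 2 (0.196) and in DESeq2 (0.0963). Exons of Nusap1, Tk1, Cdc45 and Gins2 overlap Oip5, Afmid, Ufd1 and Gse1.

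Ribosomal protein genes rose in part. Of 30 tested members 15 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 0.32. The list passed camera (adjusted p = 0.0166) at the preset correlation of 0.01, while its estimated correlation was 0.518. The call was lost, with adjusted p = 0.971 with an estimated correlation, and without EV replicate 2, with adjusted p = 0.0834 by camera, and fry gave adjusted p = 0.146 against no change. Rps9 had 4968 ± 729.9 CPM in EV and 8177 ± 775 CPM in R882H (0.72 ± 0.16), Rpl37 1132 ± 265 CPM in EV and 2238 ± 52.6 CPM in R882H (0.98 ± 0.15) and Rpl22 1126 ± 287 CPM in EV and 2014 ± 20.9 CPM in R882H (0.84 ± 0.16). Rpl4 (0.40 ± 0.15) lost its call with the replicate block (0.0815), without EV replicate 2 (0.0531), without R882H replicate 1 (0.142) and without R882H replicate 2 (0.208). Rpl32 (0.43 ± 0.15) lost it without EV replicate 2 (0.0658), without R882H replicate 1 (0.198) and without R882H replicate 2 (0.0868), and Rpl11 (0.85 ± 0.16) in DESeq2 (0.0737), with a log2 fold change of 0.53 without EV replicate 2. Of 11 tested immediate early and heat shock genes, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.687). Fos (2.63 ± 0.57), Jun (1.09 ± 0.33), Zfp36 (0.72 ± 0.23) and the chaperone gene Dnajb1 (0.67 ± 0.14) rose and Egr1 (−0.76 ± 0.30) fell. Fos lost its call without R882H replicate 1 (0.0942), and Jun without EV replicate 2 (0.0523), without R882H replicate 1 (0.0923) and in DESeq2 (0.140). Zfp36 lost it without EV replicate 1 (0.0870), without R882H replicate 2 (0.0810) and in DESeq2 (0.165), and Egr1 without EV replicate 2 (0.246), without R882H replicate 2 (0.392, log2 fold change −0.44) and in DESeq2 (0.258), with a log2 fold change of −1.16 without R882H replicate 1. Of 12 tested mitochondrially encoded genes, mt-Nd5 (0.47 ± 0.15) and mt-Co1 (0.45 ± 0.15) rose and mt-Nd2 (−0.68 ± 0.14) fell, also when adjusted over the list alone (camera adjusted p = 0.945), and mt-Nd2 lost its call without R882H replicate 1 (0.0552). For mt-Nd5 the call ended without EV replicate 2 (0.156, log2 fold change 0.24) and without R882H replicate 2 (0.131), with a log2 fold change of 0.73 without EV replicate 1, and for mt-Co1 without R882H replicate 1 (0.160) and without R882H replicate 2 (0.0887). The most abundant of them, mt-Nd4, had 18603 ± 508 CPM in EV and 13787 ± 4361 CPM in R882H (edgeR adjusted p = 0.0538), and it passed as lower with library size only (0.0204), in limma-voom (0.0391) and without R882H replicate 2 (0.0118, log2 fold change −0.78). Whether reads of ribosomal protein pseudogenes were separated was not tested, and exons of mt-Nd2, mt-Nd5 and mt-Co1 overlap mt-Tw, mt-Nd6 and mt-Ts1.

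**Figure D3:**
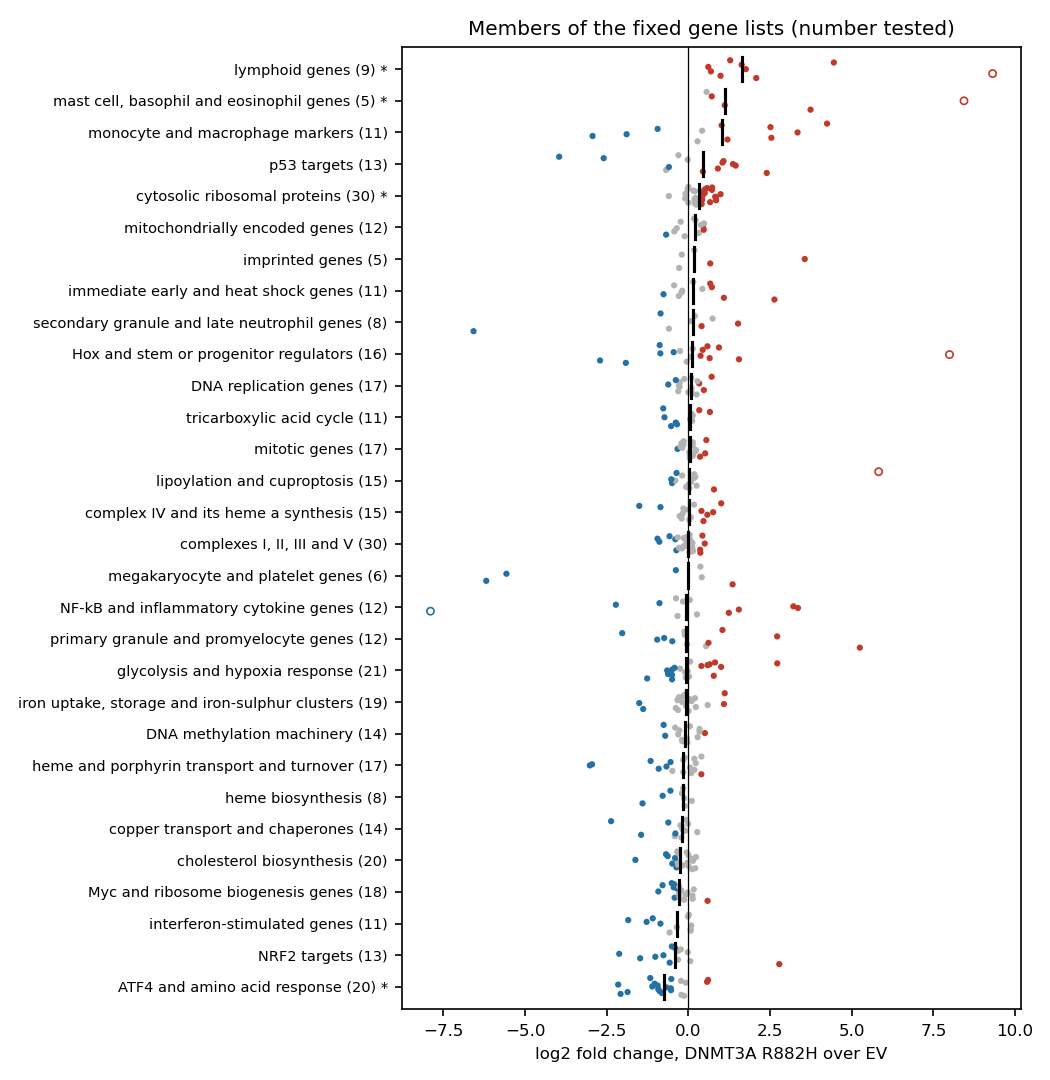
Log2 fold change (R882H over EV) of each tested member of the gene lists with at least 5 tested members, with red and blue points for members that rose and fell by edgeR, grey points for members not called, black bars for list medians and the number tested in brackets. Open points mark members with at most 3 counts in a group, whose fitted fold is no bound; asterisks mark the 4 lists past the camera test, of which lymphoid genes have the highest median (1.63) and ATF4 genes the lowest (−0.74).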

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

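Leaving out genes with overlapping exons was chosen after the results were seen; the other alternatives were chosen before the data were examined. None of the 166 called named genes and none of the 4 lists past camera reversed direction under the alternatives run for them; set tests were not run with robust=FALSE, limma-voom, DESeq2 or glmTreat. The number of higher genes lay between 1297 and 2326 and of lower genes between 1412 and 2301. Leaving out 1 library gave 1508 to 2065 higher and 1446 to 2168 lower genes, with the lone library assumed to vary like the other group, and DESeq2 called 1297 and 1412, of which 1266 and 1382 were also called by edgeR. The cause of the lower DESeq2 count was not tested. Without the 3501 genes with overlapping exons, 1560 were higher and 1577 lower among 7943. Scalings moved the share of higher calls between 47.5% and 49.9% and no median by over 0.1.

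With the replicate number as a block, 2196 genes were higher and 2229 lower, of which 2140 and 2174 were also called without the block. It called 4 lists, and the heme biosynthesis median was −0.18 (adjusted p = 0.175). Samples with the same number deviated from their group means with a correlation of −0.0026, so the numbers gave no sign of pairing. Of the 184 named genes with a test, 4 lost the call under the block.

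The count of lists past the set test was 4 of 30 with camera, 8 of 33 without a low-count filter, 9 with fry, which asks another question (change against none), and 0 with an estimated correlation; leaving out 1 library gave 4 to 5 and leaving out genes with overlapping exons 5 of 28. An estimated correlation also missed the planted list in the simulation, so a call lost under it can reflect low power. Genes were drawn independently there, so the simulation cannot check the preset of 0.01 where genes vary together. The ribosomal list had an estimated correlation of 0.518 (unadjusted p = 0.476 by camera with that estimate), so its call rests on the preset. Estimates were −0.036 for the mast cell, 0.015 for the lymphoid and 0.054 for the ATF4 list. Without a filter the monocyte, interferon, NRF2 and fibroblast lists were added, and fry added the monocyte, interferon, copper, Myc, primary granule and cholesterol lists and lost the ribosomal one (adjusted p = 0.146). For heme biosynthesis the adjusted p stayed above 0.05 in every alternative (0.0684 with fry to 0.702 with an estimated correlation), and its median lay between −0.31 and −0.17. Of the 166 called named genes, 52 lost the call under at least 1 alternative, 27 of them only when a library was left out. Leaving out R882H replicate 2 ended the most, 34. At this depth and with 2 libraries per group, the simulated recovery was 34% at 1.5-fold. The simulation made 157 calls, against 4435 in the data, so its adjusted threshold was stricter. That recovery therefore does not carry over to these data.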

Other observations

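All tests in this part were chosen after the results were seen. Grouping tested genes by shared symbol gave 259 families with at least 6 members, tested with camera. Those past the threshold were Zfp, Rpl, Acot and the protocadherin gamma families Pcdhga and Pcdhgb, and none passed with an estimated correlation. Of 72 tested Rpl genes 30 rose and 1 fell (camera adjusted p = 0.00253). Of 59 tested Rps genes 26 rose and 4 fell, and that family did not pass (camera adjusted p = 0.0539). Of 255 tested zinc finger genes named Zfp, 68 rose and 16 fell, with a median log2 fold change of 0.34 (camera adjusted p = 0.00253; adjusted p = 0.996 with an estimated correlation). Among them Zfp36l2, an RNA-binding protein gene, rose by 1.84 ± 0.14 on the log2 scale, Zfp422 by 1.21 ± 0.14, Zfp397 by 1.52 ± 0.18 and Zfp770 by 1.93 ± 0.23, while Zfp503 had −2.65 ± 0.22 (edgeR adjusted p at most 2.09e-08 for each, SE from n = 2 per group).

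Of 9 tested acyl-CoA thioesterase (Acot) genes 6 fell, 3 were not called and none rose, with a median log2 fold change of −1.25 (camera adjusted p = 0.0183; adjusted p = 0.996 with an estimated correlation). Acot1 (chromosome 12, 84009490 to 84018371) had 488 ± 8.31 CPM in EV and 156 ± 0.761 CPM in R882H (−1.64 ± 0.13), Acot2 −1.99 ± 0.16, Acot3 −2.84 ± 0.17 and Acot4 −2.38 ± 0.38, each with both R882H libraries below both EV libraries. These 4 lie side by side on chromosome 12 and are similar in sequence, so reads shared between them cannot be excluded; 4 of the 9 have exons that overlap another gene. The protocadherin gamma genes, whose medians were 451, 579, 177 and 180 counts, count as 1 measurement because of their shared exons.

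Y-linked transcripts in the R882H libraries came to 197 counts against 6 in EV. Misassigned reads of the X-linked homologues are argued against, because the ratio of Y to X homologue counts was 34.0-fold higher in R882H than in EV (exact 95% interval 15.4 to 93.9), where misassignment predicts equal ratios. A wholly male R882H culture with a single X is argued against by Xist, whose level in R882H was 1.11 times that in EV (0.922 to 1.34 at 2 standard errors). The Y genes stood at 2.82% of their X homologues. That could come from male cells making up part of the R882H cultures or from reads of a male library outside the series. By library the share was 3.03% and 2.59% in R882H replicates 1 and 2, and 0.0558% and 0.110% in EV replicates 1 and 2. Male cells in both R882H cultures predict this pattern. Reads of an outside library would have had to reach both R882H libraries at a similar level and largely miss both EV libraries. The counts do not exclude that, so the choice between these 2 sources was not settled. Whether such a source also gave part of the rises that started from almost no EV transcript was not tested.

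Of the 11444 tested genes 4435 differed, some of them near the detection limit in 1 group. Fibroblasts in the EV cultures are argued against as the source of Thy1, since Col1a1, Col1a2, Col3a1, Dcn, Lum and Sparc together had 4 EV counts beside 7347 of Thy1. Megakaryocytes or platelets are argued against for Pf4 and Ppbp, since the lowest log2 fold change among the 4 other tested members was −0.39 (Itgb3). Gain or loss of whole chromosomes in all cells of a group is argued against. The largest median was 0.17 (chromosome X) among chromosomes with at least 100 tested genes. Changes in part of the cells or of a chromosome shift a median less, and these medians cannot exclude them. The Y-linked transcripts, with 197 counts in R882H against 6 in EV, are a difference in cell or library content between the groups. Their source was left unsettled above. Whether the groups also differ for other reasons apart from the vector, such as separate origin or selection of clones, stays open. The labels do not say whether the libraries of a vector came from more than 1 transduced line. A between-group correlation of 0.900 may reflect either such reasons or the variant, which cannot be told apart in this design.

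For the lymphoid genes higher in the R882H libraries, mature B cells are argued against, because Cd74, H2-Aa and Ms4a1 together had 4 R882H counts beside 231 of Cd79a. Early B-lineage cells as part of the cultures cannot be told apart from an early lymphoid programme in the cells themselves. The early marker Il7r had 0 and 0 counts in EV and 2 and 2 in R882H, too near the detection limit to decide. Transcripts of Igll1, Ebf1 and Dntt were also present in EV, whereas Pax5 had no counts there. An effect of the DNMT3A variant, which the design names, stays among the untested explanations.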
